A study of Caenorhabditis elegans with 6 samples.

How the data were processed

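Total RNA of whole Caenorhabditis elegans was sequenced in 6 libraries, 3 labelled control and 3 labelled mutant, after 24 hours on Pseudomonas aeruginosa PA14 at 25 °C. Per the labels' protocols, residual DNA was removed with TURBO DNase and libraries were made with standard Illumina protocols. The libraries were grouped by their titles and genotype labels, and no batch, date or pairing is given.

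Counting with HTSeq and testing with DESeq2 are named in the submitters' processing notes, with no version or setting. The aligner, genome build, annotation, use of strand and handling of reads shared between genes are not given in the sources used here. The deposited signal values are size-factor normalized read counts, 1 column per library. Each value above 0 was a whole number of reads times 1 constant per library within 0.01 read for 100% of the values, so whole reads were recovered by dividing by that constant. The authors' deposited table of the same comparison gives a mean signal over the 6 libraries, a log2 fold change with its standard error, a Wald statistic (the score of DESeq2's test) and a p-value with its adjusted value. The direction of the authors' deposited log2 values was checked against the normalized counts, with 100% in the same direction, mutant over control.

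The deposited table holds 46908 genes, of which 22503 had a read in any library and 24405 had none. Of its gene IDs, 44056 (93.9%) matched the gene names table and 46860 (99.9%) matched the Ensembl release 115 annotation of WBcel235. Positions were taken by gene ID from that annotation, since the authors' build is not stated. The recovered depth was 17.4 to 26.6 M reads per library. Size factors were 0.880, 0.902 and 0.927 in control and 0.860, 1.24 and 1.36 in mutant. Total normalized values were 19.7, 19.7 and 20.4 M in control and 30.9, 18.7 and 19.3 M in mutant. The 10 most abundant genes took 11.3, 11.2 and 11.4% of the reads in control and 27.8, 19.4 and 14.0% in mutant.

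Genes with a mean normalized value of at least 10 over the 6 libraries were tested, 13475 in all, of which 13467 matched the annotation. Because the deposited unit is normalized, the test was limma (3.58.1, R 4.3.3) with an intensity trend on log2 of the normalized value plus 1, two-sided, with group as the only term and Benjamini-Hochberg adjustment at 0.05. fer-1 fell below the filter and was not tested. Data were simulated for 13475 genes from the control libraries' means and the 6 libraries' sizes. On them limma recovered 7% of 100 changes of 1 and 61% of 100 changes of 2 on the log2 scale, with 4 false calls of 72. edgeR recovered 8% and 65%, with 9 false calls of 82, and DESeq2 21% and 81%, with 26 of 128. The simulation left all other genes unchanged and gave both groups the same spread. Its rates therefore do not describe the real comparison, where 53.1% of the genes were called and the spread differed between groups.

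The genes to name were set by a rule: mtm-10, fer-1, unc-86 and odr-1; in each direction the 12 genes with a public name and the 3 with only a sequence name that changed most, among called genes with a mean of at least 50 and no overlap between groups; and up to 4 members with the smallest p of each list. The 39 gene lists came from textbook biology and were matched by public name, with families taken by name prefix. Members absent from the table or below the filter were dropped. camera with a preset inter-gene correlation of 0.01 tested the 38 lists with at least 5 measured members. Fisher's exact test, two-sided, compared called genes within 1 Mb of mtm-10 and on each chromosome with the rest. A gene with no control read was set against a floor of 3 reads per library.

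The replicate numbers were checked as a possible pairing. After removing group means, the correlations across genes between control and mutant libraries of the same number were -0.060, -0.081 and 0.033, so no pairing was used. Alternatives were another pseudocount, filter, scaling or spread estimate, the replicate number as a block, edgeR 4.0.16 and DESeq2 1.42.0 on recovered reads, leaving out each library, camera with an estimated correlation, fry, and other windows. Tables were read with Python 3.11 and pandas 2.3.3.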

Results

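RNA-seq of whole Caenorhabditis elegans was compared between 6 libraries, 3 labelled control and 3 labelled mutant. All animals were synchronized by a 3-hour egg lay, grown at 20 °C to young adults and then kept for 24 hours at 25 °C on Pseudomonas aeruginosa PA14, a bacterium that infects and kills the worm. By the labels, the control animals carried kyIs262, an integrated transgene, and a fer-1 mutation. The mutant animals carried a mutation in Y48G1C.10 and fer-1, with no transgene in the label. Control libraries held 17371146, 17745383 and 18907335 reads in genes, and mutant libraries 26571415, 23073269 and 26208905. The comparison asks how the transcriptome of infected animals differs between the groups. By the labels the groups differ in kyIs262 as well as in the Y48G1C.10 mutation, so no difference can be assigned to the mutation alone. The labels do not say that the libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. With 3 libraries against 3, an exact permutation test of a single gene cannot go below a p of 0.1, so genes were tested with limma's model across all genes. Library pairs of a group differed by more than sampling noise, with a chi-square per degree of freedom from 7.97 to 31.5 for control pairs and from 151 to 387 for mutant pairs, and each library was counted as 1 sample. Across genes, Pearson's r was 0.977 to 0.988 within control, 0.921 to 0.952 within mutant and 0.797 to 0.888 between the groups. The first principal component, with 75.6% of the variance, separated the groups, and the second separated mutant library 1 (-77.2) from mutant library 3 (52.1). The median SD of a gene on the log2 scale was 0.197 in control and 0.466 in mutant.

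The gene named in the mutant genotype was lower in the mutant libraries. Y48G1C.10, which the annotation names mtm-10 after the myotubularin family of lipid phosphatases (WBGene00021683), was at 843 ± 79.6 (SD, n = 3) normalized reads in control and 526 ± 49.1 (SD, n = 3) in mutant, 0.623 times the control mean. It lies on chromosome I, from 81193 to 91296, on the plus strand of WBcel235, and the counts cover the whole gene. Its neighbours csk-1 on one side and pid-2 and Y48G1C.8 on the other, named after their values were seen, fell as well, with log2 fold changes of -0.63, -0.86 and -0.92, while natc-3, Y48G1C.6 and Y48G1C.13 did not pass in limma, so the fall was not particular to this gene. odr-1 and unc-86 were low in the libraries labelled control and rose in those labelled mutant. By general knowledge of the strain, not by the labels, the promoters of these genes drive the markers of kyIs262, which the labels give to the control. odr-1, a guanylyl cyclase of olfactory neurons, had 1.14, 1.11 and 5.4 normalized reads in control and 371, 362 and 239 in mutant. unc-86, a POU homeobox gene of neurons, had 11.4, 3.33 and 6.47 in control and 81.4, 210 and 168 in mutant.

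The log2 fold change of mtm-10 was -0.68 with an SE of 0.21, with an adjusted p of 0.0226 from limma, and mtm-10 was lower in all 3 mutant libraries than in any control library. The call was lost without control library 1, 2 or 3, where the mtm-10 log2 fold change was -0.75, -0.69 or -0.61 and limma's adjusted p was 0.0686, 0.0948 or 0.101. Calls over all genes also fell there, from 7151 to 4472, 4217 and 4442, so the loss is not particular to mtm-10. With TMM rescaling its log2 fold change was -0.50 (limma adjusted p 0.0461), and by edgeR -0.50 (adjusted p 0.0478). The adjusted p of mtm-10 ranged from 0.0126 to 0.101 over 17 alternative settings. By limma, the log2 fold change of odr-1 was 6.70 (SE 0.54, adjusted p 8.4e-05) and that of unc-86 was 4.28 (SE 0.55, adjusted p 0.000717). The genes annotated just upstream of both rose as well. glb-20, a globin-related gene that lies next to odr-1 on the side of its promoter and on the same strand of chromosome X (13552339 to 13556166, with odr-1 from 13544729 to 13550990), had 19.3, 22.2 and 37.8 normalized reads in control and 8045, 9732 and 3655 in mutant (log2 fold change 7.97, SE 0.40). C30A5.16, on chromosome III from 8218219 to 8219342, upstream of unc-86 (8212740 to 8216336) on the opposite strand, had no read in the 3 control libraries and 102, 221 and 229 normalized reads in mutant. Taking 3 reads per control library as the floor, its mean was at least 55.4-fold higher. The noncoding gene C30A5.11 (8216458 to 8216570), named after its values were seen, had no control read and 211, 106 and 53.8 normalized reads in mutant, at least 37.1-fold higher. Of the nearest protein-coding genes beyond the other ends, cah-4 past odr-1 had a log2 fold change of 0.88. C30A5.10 past unc-86 had no control read and 6.98, 37.2 and 34.6 normalized reads in mutant, at least 7.90-fold higher. Floors and intervals cover counting error only. Without a stated use of strand in the counting, reads of overlapping genes cannot be told apart. fer-1, mutated in both groups by the labels, had 4, 9 and 7 reads in control and 3, 9 and 24 in mutant, below the filter of the test.

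**Figure D1:**
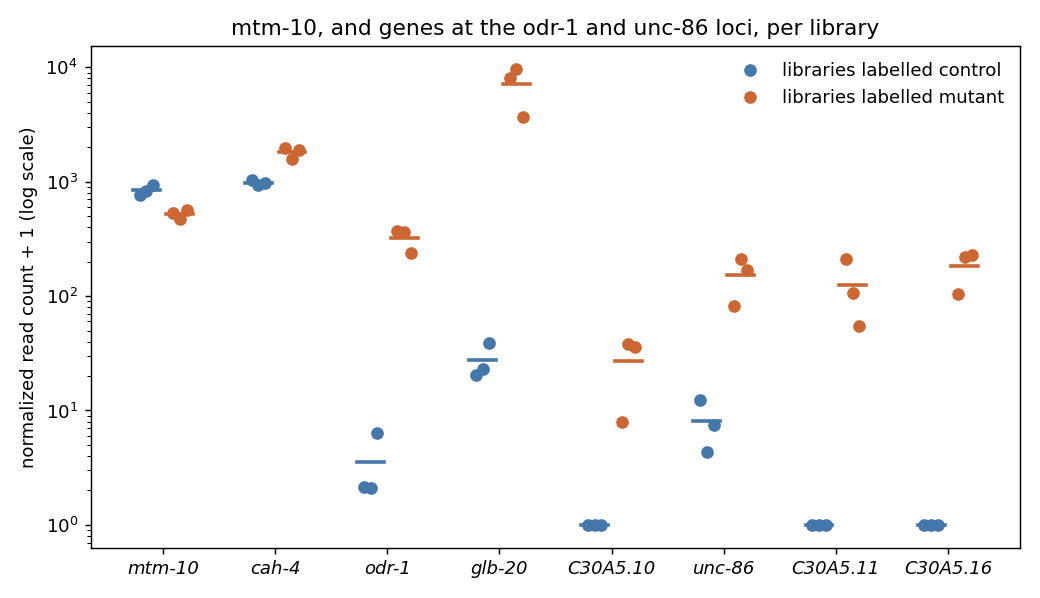
Normalized read count plus 1, on a log axis, for each library of mtm-10 and of genes at the odr-1 locus (cah-4, odr-1, glb-20) and the unc-86 locus (C30A5.10, unc-86, C30A5.11, C30A5.16). Points are the 3 libraries labelled control and the 3 labelled mutant, and bars are group means; mtm-10 is lower in mutant (843 against 526) while odr-1 (2.55 against 324) and glb-20 (26.4 against 7144) are higher.

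Many genes differed between the groups. Collagens made up most of the genes with a public name that rose most in mutant, and those that fell most included T-box, F-box and Skp1-related genes. Among genes with a public name, the 12 with the largest rise were col-147, sqt-1, dpy-13, col-17, dpy-5, col-167, col-107, rol-8 and dpy-8, all collagens of the cuticle, with grl-5, a ground-like gene, the cuticulin gene cut-2 and glb-20. dpy-13 was at 2.23 ± 1.15 (SD, n = 3) normalized reads in control and 2121 ± 1914 (SD, n = 3) in mutant, and cut-2 rose by 7.36 on the log2 scale to 2574 ± 962 (SD, n = 3). The mutant libraries differed in these collagens: col-147 had 177, 7401 and 3401 normalized reads in mutant libraries 1, 2 and 3, against 1.14, 1.11 and 10.8 in control. sqt-1 had 2 reads in all control libraries together and grl-5 had 1, so their ratios, 1711 (95% interval 473 to 14135) and 857 (154 to 33897), are set by counting error. The 12 largest falls were in pap-2, tbx-38, pap-3, dct-13, pes-10, tbx-37, fbxb-17, fbxb-119, fbxb-81, bath-31, ccch-2 and skr-9. pap-2 fell from 607 ± 43.1 to 7.54 ± 2.71 normalized reads (SD, n = 3 each), a log2 fold change of -6.21. The T-box genes of the early embryo tbx-37 and tbx-38 had log2 fold changes of -4.88 and -5.25. skr-9, a Skp1-related gene, fell from 1558 to 64.2 normalized reads, and bath-31, a BTB and MATH domain gene, from 247 ± 40.5 to 8.75 ± 0.611 (SD, n = 3 each). Of genes with only a sequence name, C30A5.16, F41F3.3 (log2 fold change 7.37) and Y47D7A.13 (7.11) rose most, and F15D4.5 (-6.27), C38D9.2 (-6.24) and the pseudogene R52.10 (-5.89) fell most. F15D4.5 fell from 4187 ± 121 (SD, n = 3) to 53.6 ± 8.5 (SD, n = 3) normalized reads. F-box, bath and collagen genes have close paralogs, and how reads shared between copies were counted is not given in the sources used here, so single members of these families are uncertain.

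By limma with Benjamini-Hochberg adjustment, 7151 of 13475 tested genes (53.1%) passed an adjusted p of 0.05, 3744 higher and 3407 lower in mutant, and 3441 of the higher and 1640 of the lower ones changed by at least 1 on the log2 scale. The libraries of the groups did not overlap for 4249 genes in the higher and 4627 in the lower direction, 65.9% of the tested genes where chance gives 10%. The gene lists, the rule for naming genes and the tests of genes, lists and positions were chosen before the data were examined. The split of the calls moved with the scaling and with the test. By limma, 52.4% of the calls were higher in mutant as deposited, 41.2% after quantile normalization (2209 higher) and 61.0% with TMM rescaling, and the median log2 fold change of all genes, against which list medians stand, was 0.10, -0.12 and 0.28. On recovered reads, 57.8% were higher by DESeq2 and 64.2% by edgeR with TMM factors. Leaving out mutant library 2 gave 2441 higher calls, and leaving out control library 1, 2 or 3 gave 1794, 1685 or 1804 lower calls.

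Most measured genes of the cuticle, skin, nerve and muscle lists rose. Of 117 measured cuticle collagen genes, 84 rose and 1 fell (85 and 1 adjusted over the list alone), with a median log2 fold change of 4.31, or 4.2 with the 8 genes that had no control read set at their lower bound, and 2.46 when genes with low values were kept. sqt-3 went from 234 to 10408 normalized reads and dpy-17 from 165 to 4874 (log2 fold changes 5.47 and 4.89). Of 17 hypodermis and seam genes, 11 rose and 1 fell (the same counts adjusted over the list alone), among them the hedgehog-related wrt-2 (6.58) and wrt-1 (5.64). Of 84 neuropeptide genes, 67 rose and 1 fell (69 and 1 adjusted over the list alone), with a median of 2.25, and flp-24 and flp-27 rose by 2.79 and 3.13. Of 26 neuronal marker genes, 20 rose and 2 fell (21 and 3 adjusted over the list alone), with a median of 2.23, including the neuropeptide-processing genes egl-21 (2.39) and sbt-1 (2.6). Of 25 muscle genes, 24 rose (24 adjusted over the list alone), with a median of 1.71, including troponin T mup-2 (2.03) and the myosin light chain gene mlc-1 (2.06). The rise was not even over the mutant libraries: the median of the collagens lay 2.48, 5.62 and 4.47 above the control mean in mutant libraries 1, 2 and 3, that of the neuronal markers 0.91, 2.69 and 2.77, and that of the muscle genes 1.64, 1.76 and 2.0. limma's camera test with a preset correlation of 0.01 called the 5 lists higher, with adjusted p from 1.4e-15 for the collagens to 0.00186 for hypodermis and seam. None held with an estimated correlation: adjusted p = 0.469 with an estimated correlation for muscle and adjusted p = 0.58 with an estimated correlation for each of the other 4. With fry, limma's rotation test, which does not set a list against the other genes, all 5 lists passed. Its adjusted p ran from 0.00457 for muscle to 0.0235 for the neuronal markers.

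In 8 lists of intestinal, immune, detoxification and proton pump genes, more genes rose than fell. Over all 13475 tested genes, 3744 rose and 3407 fell. Of 14 genes that depend on the PMK-1 p38 pathway in infection, 8 rose and none fell (9 adjusted over the list alone), with a median log2 fold change of 1.30. irg-5 rose from 844 ± 967 to 7935 ± 4588 (SD, n = 3 each) normalized reads (3.73) and dod-24 from 8962 ± 2327 to 41446 ± 18347 (SD, n = 3 each, 2.13). Of 20 saposin-like genes 11 rose (12 adjusted over the list alone), with a median of 1.31, among them spp-14 (1.33) and spp-22 (2.16). Of the C-type lectin genes 34 rose, 8 fell and 59 did not pass (28 rose and 7 fell adjusted over the list alone), with a median of 1.01, with clec-78 (3.90) and clec-72 (3.27) among the risers and clec-223 falling by 1.88 on the log2 scale. Of 19 intracellular pathogen response genes 6 rose (6 adjusted over the list alone), among them pals-18 (1.64) and skr-3 (1.52). Of 32 glutathione S-transferase genes 15 rose (15 adjusted over the list alone), such as gst-20 (2.19) and gst-38 (3.49), and of 53 UDP-glucuronosyltransferase genes 20 rose (16 adjusted over the list alone), such as ugt-57 (4.51) and ugt-54 (1.65). Of 19 intestinal marker genes 11 rose (11 adjusted over the list alone), with a median of 1.26, including the intermediate filament gene ifb-2 (2.15) and the brush border actin act-5 (1.97). Of 19 vacuolar ATPase genes 16 rose and 1, vha-7, fell (17 and 1 adjusted over the list alone), and vha-5 rose by 2.16.

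Yolk genes and the mutant libraries varied alongside these groups. The vitellogenin genes took 8.38, 8.37 and 8.5% of the reads in control and 21, 15.9 and 10.1% in mutant libraries 1, 2 and 3. Their median lay 1.56, 0.77 and -0.20 from the control mean in those mutant libraries. In the authors' deposited table vit-6 and vit-2 passed (log2 fold changes 1.26 and 1.23, DESeq2 adjusted p 0.00523 and 0.00528). There vit-4 and vit-5 did not pass (DESeq2 adjusted p 0.0705 and 0.0537). None of the 6 genes passed in limma, with a median log2 fold change of 0.71. After quantile normalization that median was 0.00. This scaling gives genes of equal rank equal values in every library, so it can hide a change of very abundant genes. The yolk median of 0.71 became 0.29 without mutant library 1 and 1.17 without mutant library 3. In the same libraries the median of the PMK-1 list lay 2.31, 1.36 and 0.51 above the control mean, that of the saposins 2.07, 1.28 and 0.43, that of the lectins 1.73, 1.06 and 0.31 and that of the intestinal markers 1.79, 1.05 and 0.66. limma's camera called all 8 lists higher, with adjusted p from 0.000663 for the glucuronosyltransferases to 0.0115 for the pathogen response genes. With an estimated correlation none held, with adjusted p = 0.635 with an estimated correlation for the intestinal markers and adjusted p = 0.58 with an estimated correlation for the other 7. The lectin call was lost with no filter on low values (limma adjusted p 0.127) and with fry (0.081), and the intestinal call with fry (0.102). The pathogen response call was lost with no filter (0.052), after quantile normalization (0.148) and without mutant library 1 (0.0546), within a range of 0.00541 to 0.58 over 16 settings. After quantile normalization the medians of the lectins, pathogen response genes and glucuronosyltransferases were 0.40, 0.38 and 0.29. The lectin median was 0.62 without mutant library 1 and 0.50 with no filter on low values, and that of the pathogen response genes 0.63 and 0.54.

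Most measured germline, oocyte and cell cycle genes fell. All 22 measured genes of the cell cycle and DNA replication fell (22 adjusted over the list alone), with a median log2 fold change of -1.18, among them cyclin B cyb-1 (-1.49) and the replication genes mcm-3 (-1.40) and pcn-1 (-1.50). Of 24 oocyte and eggshell genes, 20 fell and none rose (21 adjusted over the list alone), with a median of -1.01, and mex-5 fell from 24414 to 9046 normalized reads (-1.46) and mex-1 from 11021 to 4287 (-1.39). Of 27 germ cell and meiosis genes, 23 fell and none rose (24 adjusted over the list alone), with a median of -0.93, among them syp-1 of the synaptonemal complex (-1.36) and the Notch receptor glp-1 (-1.21). The medians of the germ cell genes lay 0.84, 1.40 and 0.49 below the control mean in mutant libraries 1, 2 and 3. limma's camera called these 3 lists lower, with adjusted p of 3.31e-08, 1.56e-06 and 1.56e-06, and adjusted p = 0.58 with an estimated correlation for each. With fry, limma's rotation test, the germ cell list had an adjusted p of 0.0532, the oocyte list 0.036 and the cell cycle list 0.0235. Only 15 of 68 sperm genes passed the filter on low values, so the list covers few of them. Among these 15, ssq-1 rose by 1.13 and spe-41 fell by 1.89. Adjusted over the list alone 0 rose and 1 fell, and camera did not call the list (adjusted p 0.588). Their median of 0.52 turned to -0.32 after quantile normalization, and was 0.22 without mutant library 1 and 0.27 with no filter on low values.

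**Figure D2:**
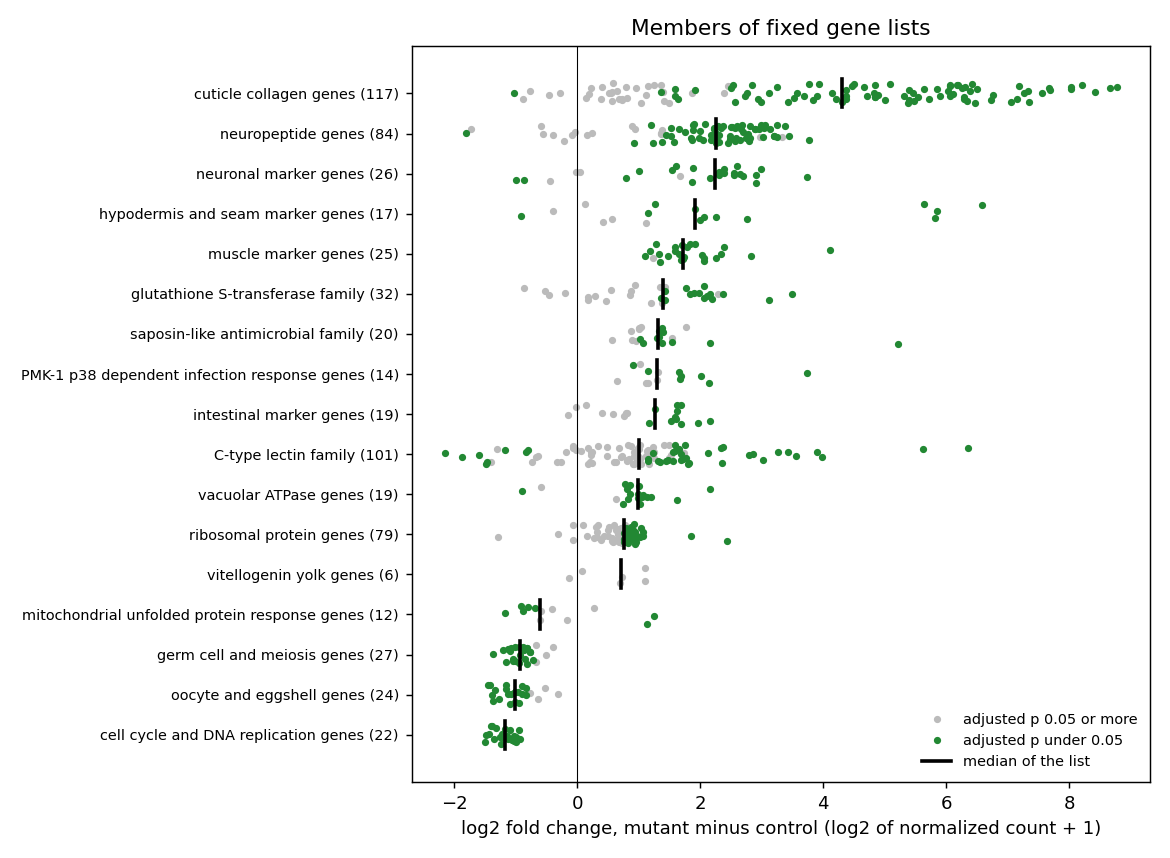
Log2 fold change of mutant over control for each measured member of 17 of the fixed gene lists, with the number of members in brackets; green points passed an adjusted p of 0.05 in limma, grey points did not, and black bars are medians. The collagens sit farthest to the right (median 4.31) and the cell cycle genes, all green, to the left of 0 (median -1.18).

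**Figure D3:**
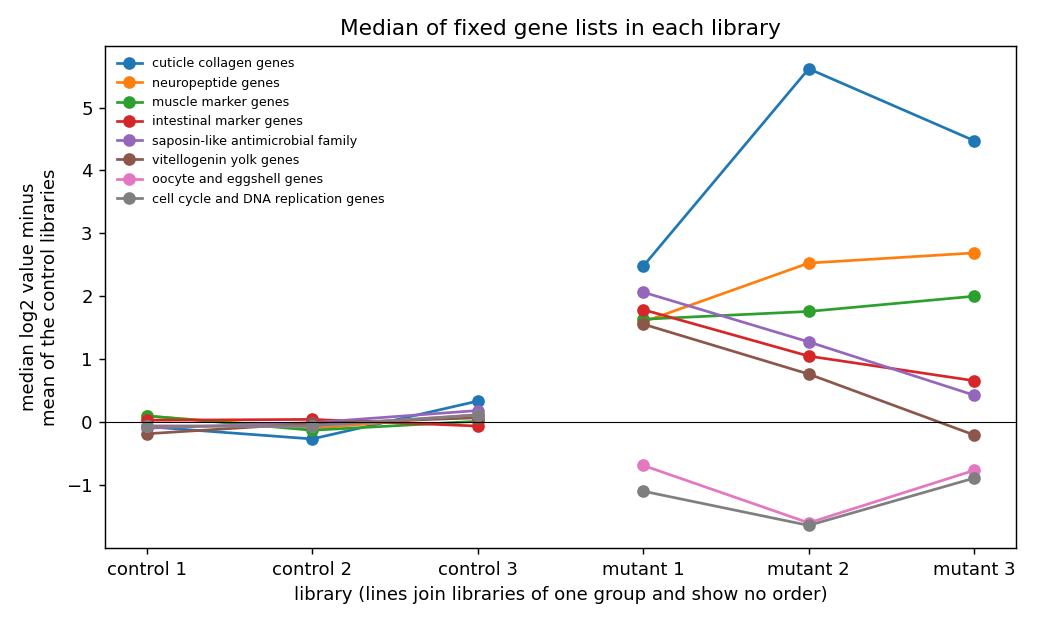
Median over each list of the log2 value minus the mean of the 3 control libraries, for each of the 6 libraries; lines join libraries of a group and show no order. Mutant library 1 has the lowest collagen median (2.48) and the highest saposin (2.07), intestinal (1.79) and yolk (1.56) medians of the mutant libraries.

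Some ribosomal protein, fatty acid and hypoxia response genes rose. Of 79 ribosomal protein genes 33 rose (2 adjusted over the list alone), with a median log2 fold change of 0.76, and rpl-11.2 and rpl-25.1 rose by 2.44 and 1.85 (camera adjusted p 8.7e-06 in limma, adjusted p = 0.728 with an estimated correlation). The ribosomal median was 0.31 after quantile normalization and 0.48 without mutant library 1, and the call was lost with fry (0.1). Of 17 fatty acid desaturation and synthesis genes 6 rose (6 adjusted over the list alone), including the stearoyl-CoA desaturase fat-6 (1.08) and the fatty acid elongase elo-2 (1.51), with a camera adjusted p of 0.0494 and adjusted p = 0.669 with an estimated correlation. Of 11 genes of the HIF-1 hypoxia response 5 rose (5 adjusted over the list alone), among them cysl-1 (1.97) and hif-1 (1.01). Its camera adjusted p was 0.0427, 0.0685 with the replicate number as a block, and adjusted p = 0.58 with an estimated correlation. The fatty acid call was lost without control library 2 or 3 or mutant library 1 (limma adjusted p 0.0879, 0.0917 and 0.134), without an intensity trend (0.0902) and with fry (0.106), within a range of 0.000175 to 0.669. The HIF-1 call was lost without control library 1, 2 or 3 or mutant library 3 (0.0553, 0.05004, 0.0835 and 0.0569), after quantile normalization (0.0811) and without an intensity trend (0.0674), within a range of 0.0161 to 0.58.

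The remaining lists were not called by limma's camera. ZIP-2 and surveillance genes had 3 risers, including irg-7 (1.93) and zip-2 (1.03), and 1 that fell, cebp-2 (-0.72), of 9 (3 and 1 adjusted over the list alone, camera adjusted p 0.259). In the innate immune signalling list 10 of 18 rose and 2 fell (10 and 2 adjusted over the list alone, 0.0924), with the kinase kgb-1 up by 1.35 and the transcription factor hlh-30 by 0.96. Of 11 lysozymes 2 rose, ilys-4 (1.70) and lys-8 (1.53), with 0 adjusted over the list alone (0.166). Of 31 caenacin, NLP and fungus-induced peptide genes 6 rose and 1 fell (4 and 1 adjusted over the list alone, 0.108), with nlp-24 at 4.23. Of 15 DAF-16 activated genes the catalase genes ctl-1 (1.22) and ctl-2 (0.90) rose and lea-1 (-1.08) fell (0 and 0 adjusted over the list alone, 0.545), and of 15 SKN-1 detoxification genes 5 rose (4 adjusted over the list alone, 0.157), with gst-5 at 1.83. Of 50 cytochrome P450 genes 15 rose and 4 fell (12 and 3 adjusted over the list alone, 0.109), with cyp-42A1 at 2.59. Of 10 coelomocyte and excretory genes 7 rose and 2 fell (8 and 2 adjusted over the list alone, 0.0841), and of 12 somatic gonad genes 4 rose and 2 fell (4 and 2 adjusted over the list alone, 0.907), with the gap junction gene inx-22 at -1.23. Of 27 histone genes 4 rose and 3 fell (3 and 1 adjusted over the list alone, 0.667), with his-71 at 1.69 and his-72 at -0.79. The histone median of -0.21 turned to 0.08 without mutant library 2 but was -0.80 after quantile normalization, -0.41 without mutant library 1 and -0.34 without mutant library 3 or control library 3. The somatic gonad median of 0.08 turned to -0.42 after quantile normalization and -0.04 without control library 3 but was 0.27 with TMM rescaling and 0.29 with no filter on low values. Some settings called further lists, among them the immune signalling genes after quantile normalization (0.00733), the P450 genes without mutant library 3 (0.014) and the peptide genes without control library 3 (0.00144), within ranges of 0.00733 to 0.58, 0.014 to 0.728 and 0.00144 to 0.845, whose upper ends came with an estimated correlation.

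Stress and mitochondrial lists went both ways. Of 12 genes of the mitochondrial unfolded protein response 5 fell, among them the chaperone gene hsp-60 (-1.18) and the protease gene lonp-1 (-0.88), and gpd-2 (1.24) and dve-1 (1.12) rose (2 higher and 6 lower adjusted over the list alone, camera adjusted p 0.142 in limma). fry called this list lower (adjusted p 0.0265), while camera gave adjusted p = 0.58 with an estimated correlation. Of 9 heat shock genes F44E5.5 rose by 2.34 and hsf-1 fell by 1.02 (1 and 1 adjusted over the list alone, 0.915), and the list's median was -0.20 where its mean was 0.38, with camera pointing lower and fry higher. That median turned to 0.81 with no filter on low values and 0.04 without mutant library 2, and was -0.39 without mutant library 1. The endoplasmic reticulum response had 1 riser, pdi-2 (0.86), and 2 genes that fell, sel-1 and ire-1, of 17 (0 and 0 adjusted over the list alone, 0.915), with a median of -0.03 and a mean of 0.13. Its median turned to 0.13 after quantile normalization, 0.15 with TMM rescaling, and 0.14 and 0.11 without mutant library 2 or 3. Of 25 autophagy genes 4 rose and 6 fell (3 and 2 adjusted over the list alone, 0.345), with the receptor sqst-1 at 1.47. Of 33 nuclear respiratory chain genes 5 rose and 1 fell, asb-1 (5 and 1 adjusted over the list alone, 0.286), and of 11 mitochondrially encoded genes MTCE.34 fell (0 adjusted over the list alone, 0.373), with 177, 132 and 269 normalized reads in control and 1.16, 0.809 and 251 in mutant. The nuclear respiratory chain list was called higher after quantile normalization (3.99e-05), within a range of 3.99e-05 to 0.966, but had adjusted p = 0.899 with an estimated correlation, and its median of 0.17 was 0.37 after quantile normalization and turned to -0.03 without mutant library 1. In the last setting the mitochondrially encoded median of -0.28 turned to 0.12, while it was -0.69 after quantile normalization, and without mutant library 3 that list was called lower (limma adjusted p 0.0359, range 0.0359 to 0.897, the latter with an estimated correlation). Of 18 lipid breakdown genes ech-7 (1.76) and hacd-1 (1.23) rose (1 adjusted over the list alone, 0.983), with a median of -0.06 and a mean of 0.23. The lipid breakdown median turned to 0.11 after quantile normalization, 0.12 with TMM rescaling, 0.28 without control library 1 and 0.81 without mutant library 3, and was -0.28 without mutant library 1. Of 4 measured metal response genes, too few for camera, cdr-1 rose by 1.81 (1 adjusted over the list alone), and mtl-2 stood at 0.41, mtl-1 at -0.28 and ttm-1 at 0.14.

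The chromosomes differed in the direction of change, and the surroundings of mtm-10 did not stand out. On the X chromosome 42.7% of 2025 tested genes rose and 12.7% fell, and on chromosome I 20.3% of 2143 rose and 35% fell. The X chromosome counts of 864 higher and 257 lower became 960 and 218 with TMM rescaling and 527 and 335 after quantile normalization. The odds of a call higher in mutant on X were 2.21 times those elsewhere (Fisher's exact test, 2-sided, adjusted p 1.8e-54 over 6 chromosomes), those of a call lower were 0.383 times (adjusted p 3.78e-50), and the odds of a call lower on chromosome I were 1.76 times those elsewhere (2.06e-27). Fisher's test counts genes as independent, though genes moved together across the libraries. Its p-values in this paragraph therefore do not measure the spread between libraries. Calls in either direction together were 55.4% of the X genes, with an adjusted p of 0.0525, and only chromosome V passed, at 50.3% (0.00926). Within 1 Mb of mtm-10, 72 of 126 genes were called (57.1%, against 53.0% outside), an odds ratio of 1.18 with a 95% interval from 0.816 to 1.71 (Fisher's exact p 0.371). Within 2 Mb the odds ratio was 0.998.

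**Figure D4:**
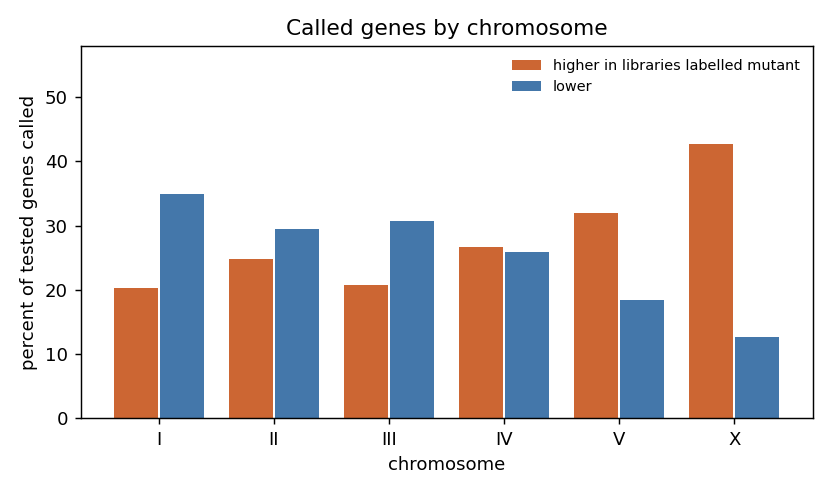
Percent of the tested genes of each chromosome called higher or lower in the libraries labelled mutant at an adjusted p of 0.05 in limma; bars start at 0. X has the highest share of higher calls (42.7%) and the lowest share of lower calls (12.7%).

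In the authors' deposited table of the same comparison, 7725 genes had an adjusted p under 0.05, 4619 higher and 3106 lower in mutant. It shared 6716 of the 7151 calls made here (93.9%), all in the same direction, and it called 1009 genes that were not called here. That table gave an adjusted p for 16736 genes, against 13475 tested here, so the 1009 may include genes not tested here. For mtm-10 the authors' deposited table gave a log2 fold change of -0.67 and an adjusted p of 0.0305, and for odr-1 a log2 fold change of 6.48.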

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

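All alternatives had been planned. Over them, 2970 values of the named genes stayed on the same side of the threshold, 125 lost it, 38 gained it and 6 turned sign; for the lists these were 552, 39 and 16, and no called list turned. Genes higher in mutant numbered 3744, 2209 after quantile normalization, which kept 63.6% of the calls, and 2441 to 3986 with 1 library left out. Genes lower in mutant numbered 3407, and 1685 to 4075 with 1 library left out. The mtm-10 log2 fold change ran from -0.75 to -0.61 with 1 library left out, where the lost calls came with fewer samples.

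With camera and an estimated correlation, 0 lists were higher in mutant and 0 lists lower in mutant. With the preset correlation these were 16 and 3, and with fry 15 and 3. The odds ratio of the position of changed genes around mtm-10 was 0.998 with a window of 2 Mb on each side. None of the genes that turned sign was called by limma with all libraries, though MTCE.16 passed without mutant replicate 3. The mtl-1 log2 fold change was 0.029 after quantile normalization and -0.72 to 0.14 with 1 library left out. The ttm-1 log2 fold change was -0.27 to 0.35 with 1 library left out. The MTCE.16 log2 fold change was 0.60 by edgeR, 0.50 by DESeq2 and -3.61 to 0.22 with 1 library left out. Other causes were not tested.

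With the replicate number as a block, 4033 genes were higher in mutant and 3142 genes lower in mutant, 93.8% of the calls were shared, and mtm-10 had a limma adjusted p of 0.0473. edgeR, DESeq2 and robust eBayes were not run for the lists.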

Other observations

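The tests of promoter copies, of exchanged labels, of a lower germline share for the cuticle genes and for the fbxb genes, of the odr-1 neuron genes with few control reads and of the ERGO-1 targets under other scalings, and the choice of the families below, were chosen after the result was seen. Of 21 gene families looked at, the F-box family fbxb, whose products are predicted to bind substrates of ubiquitin ligases, had 86 measured members, of which 78 fell and none rose, with a median log2 fold change of -2.91 (73 fell with TMM rescaling and 83 after quantile normalization). Of 30 fbxc genes 19 fell and 3 rose, and of 18 Skp1-related skr genes 11 fell and 3 rose (Fisher's exact test, adjusted p 7.13e-05 and 0.00441 over the families). Counts in the other F-box and MATH families were mixed as deposited, and no test compared families. Of 33 bath genes 11 fell and 4 rose, with a median of -0.73, or 18 and 2 with a median of -1.17 after quantile normalization. Of 103 fbxa genes 20 rose and 13 fell, with a median of 0.71 that turned to -0.15 after quantile normalization (3 rose and 16 fell). Of 20 math genes 5 rose and 1 fell, with a median of 0.59 that turned to -0.22. By Fisher's exact test bath genes passed in neither direction (adjusted p 0.0846 for higher and 0.402 for lower), nor did math genes (0.0704 for lower). Fewer fbxa genes fell than elsewhere (Fisher's adjusted p 0.00604). Fisher's test counts the genes of a family as independent. Of 348 tested pseudogenes 135 fell and 14 rose, or 226 and 6 after quantile normalization. Reads shared between paralogs leave single members of these families uncertain. Of 171 nuclear hormone receptor nhr genes 84 rose and 6 fell, with a median of 1.02, but 19 and 11 after quantile normalization, with a median of 0.28. Of 31 ligand-gated channel lgc genes 21 rose and none fell, with a median of 1.53, but 11 rose after quantile normalization, with a median of 0.61. Of the moulting and hedgehog-related families, all 8 mlt genes and 8 of 10 grl genes rose, with medians of 1.88 and 3.72; after quantile normalization 3 and 7 passed, with medians of 1.53 and 3.00.

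Lists written for the tests below held further genes. Of 18 measured zygotic genes of the early embryo 12 fell, among them vet-1 (-4.04) and sdz-26 (-4.39), and 2 rose, pha-4 (2.11) and ceh-27 (4.71). Of 33 late embryonic and moulting genes that are not collagens 29 rose and none fell, among them grl-7 (6.70) and lpr-3 (5.54). Of 16 measured genes that depend on unc-86 in touch and serotonergic neurons 11 rose and 1 fell, with a median of 2.03, or 1.37 after quantile normalization.

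The odr-1 and unc-86 reads were higher in the libraries labelled mutant, while the label gives kyIs262 to the control. More RNA of the odr-1 neurons stays open as a cause of the odr-1 reads. odr-1 lay 4.72 above the median of 1.98 of 14 other genes of these neurons, some with a baseline that would hide a small share, and 3.70 above the median of 3.00 (SD 1.27) of the 8 with a control mean under 20. From reads, the median ratio of these 8 was 10.6, against 122.3 (95% counting interval 59.1 to 305) for odr-1, and 5 of them had an interval that ended below 59.1. Those 5 had control means from 6.28 (rgs-3) to 13.4 (nlp-5), against 2.55 for odr-1, so a baseline could still hide a share. The genes with control means below that of odr-1 had intervals that reached past 59.1. lim-4, with 1 control read, had a ratio of 109 (19.3 to 4337), and ceh-36 had 20.4 (8.52 to 63.9). gpa-2, with no control read, had an interval from 31.7, and at least 12.04 against the floor of 3 reads per library. Copies of the promoter regions in the libraries labelled mutant stay open and are not supported by a test: the upstream genes glb-20 and C30A5.16 lay at the 99.9th percentile of all tested genes or above, but these ranks were known before the test, and C30A5.16 had no control read. An exchange of labels stays open too: mtm-10 at -0.68 went with the labels, but the 5th percentile of the germ cell genes was -1.19, so its fall was not larger than theirs.

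The cuticle genes were higher and the germline and early embryonic genes lower in the libraries labelled mutant. Scaling is argued against, as the germ cell median stayed at -0.72 or below and the collagen median at 3.46 or above under TMM and quantile scaling. A lower share of germline RNA alone is argued against as well, since the collagen and intestinal medians differed by 3.05, with an SD of the intestinal genes of 0.69. Later embryos or larvae in the mutant animals, with early embryos in the control animals, may account for it. The medians were -2.47 for the early embryonic genes and 3.20 for the late embryonic and moulting genes. The latter are cuticle genes as well, so their rise restates part of the pattern and cannot decide this. An effect of the mutation on the adults' own cuticle, nerve or germline genes was not tested apart from such embryos or larvae.

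Pseudogenes and fbxb genes were lower in the libraries labelled mutant. Weaker silencing by ERGO-1 class small RNAs in the control libraries stays open: of 15 measured target genes 3 rose, 3 fell and 9 did not pass, with a median of 0.46. That median lay above the germ cell median by 1.39 as deposited and with TMM rescaling, just beyond their SD of 1.35 and 1.36, which goes against it, but by 0.55 after quantile normalization, within an SD of 1.33, and the targets went both ways, from -3.68 for F52D2.6 to 1.67 for W04B5.1. For fbxb, a lower share of germline RNA alone is argued against. The median of all 86 measured fbxb genes was -2.91, and the lowest germ cell, oocyte or cell cycle gene stood at -1.50. Of the 78 fbxb genes that fell, 94.9% (95% interval 87.4 to 98.6) fell by more than any of those genes. The interval counts paralogs as independent, though they may share reads and were kept because they fell. For the pseudogenes a lower germline share alone stays open. The median of all 348 tested pseudogenes was -0.86, beside -0.93 for the germ cell genes, but -1.66 beside -0.72 after quantile normalization. Of the 135 called lower, 51.1% fell by more than any germ cell, oocyte or cell cycle gene (interval 42.4 to 59.8). That percent cannot decide, since these pseudogenes were kept because they fell. A difference of embryonic stage, weighed above for the cuticle genes, was not tested for fbxb or the pseudogenes. The median of the 18 early embryonic zygotic genes was -2.47, beside -2.91 for fbxb. An effect of the mutation was not tested apart from these causes.

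Among 10 splits of the 6 libraries into 3 and 3, 1 gave as many called genes, the real one with 7151, and the highest other gave 0 by limma. Each other split mixes the groups, which puts their large difference into the spread within its sides. Its 0 calls therefore say little about chance, and the splits are too few for a share under 0.05.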
